A study of Mus musculus with 7 samples.

How the data were processed

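Total RNA of the mouse erythroid cell line G1E was measured on 7 Affymetrix Mouse Gene 2.0 ST arrays in the transcript version, 3 from control cells and 4 from cells in which Lockd had been deleted with CRISPR/Cas9, per the labels' protocols and the series' design text. The RNA was amplified, copied into single-stranded cDNA, fragmented and labelled with biotin, per the labels' protocols. The deposited values are log2 expression values that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, sets the arrays to a common distribution and summarises the probes of each probeset. The version of the software, the array library files and the genome build behind the probesets are not given in the sources used here. The log2 scale was read from the values, which ran from 1.87 to 14.01 with column medians between 5.417 and 5.463. RMA values have no detection call, so a low value was not read as absence. All 7 columns of per-array values were used.

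Groups and replicate numbers came from the sample titles. The series' design text calls the samples clones of the line, and the labels do not say whether the replicates came from separate cultures. The p-values then measure only the spread between these samples, which may be technical in part. No pair of arrays held identical values. The number of arrays limits the precision.

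The value table held 41345 probesets. The platform annotation paired 23521 of them with exactly 1 gene symbol, and these were tested. It gave several symbols for 1814 probesets and did not list 16010. No gene was named from a probeset with several symbols. Of the tested probesets, 23328 had a gene ID in the gene table of the assembly GRCm38.p6, and all 23328 of them had an equal symbol there. That table was used only for names and for which genes neighbour each other. No coordinates are given, because the build behind the array is not named. The tested probesets covered 22180 genes, and a gene with several probesets was represented in gene counts and gene lists by the probeset with the highest mean over all 7 arrays.

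Differences are deletion minus control on the log2 scale. They were tested in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with both groups in a single fit, two-sided, with Benjamini-Hochberg adjustment over the tested probesets and a threshold of adjusted p under 0.05. No filter on level and no covariate was used. Intervals are at 95% confidence. Lockd and Cdkn1b were also tested with an exact permutation test over the 35 ways to split 7 arrays into 3 and 4. With the smaller tail doubled, its smallest possible two-sided p is 0.0571, so this form cannot pass 0.05 with these arrays. Counted by the size of the difference in either direction, a form added after seeing the data, the smallest possible p is 0.0286.

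The 26 gene lists were tested with limma's camera at its preset correlation of 0.01 on gene values, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. Camera with a correlation estimated from the data and limma's fry were the alternatives. The percentile of a list's median was taken among 10000 random lists of the same size matched on mean level. The lists were Lockd neighbours, CDK inhibitors, cyclins with CDKs and pocket proteins, S phase and DNA replication, G2 and mitosis, erythroid, heme biosynthesis and iron, progenitor, megakaryocyte, mast cell and basophil, myeloid, lymphoid, pluripotency, stromal and endothelial, p53 targets, interferon response, MHC class I and II, unfolded protein and integrated stress response, glycolysis and hypoxia, cholesterol biosynthesis, apoptosis regulators, FoxO and quiescence, ribosomal proteins, replication-dependent histones, Y-linked and immediate early genes.

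The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Lockd, Cdkn1b and their neighbours. It then named the largest differences past the threshold among genes whose groups did not overlap or, with under 3 passing, the 5 largest in each direction as values that did not pass, leaving out predicted genes. It last named up to 3 passing members of each list or, with none, the member with the smallest p. Other genes named as examples were chosen after their values were seen.

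The fit was tested on simulated data built on the 23521 probesets. With 200 probesets changed per run over 20 runs, it recovered 61.7% of those changed by 0.5 on the log2 scale, 98.6% at 1, 99.1% at 1.5 and 99.8% at 2, with on average 8.9 false calls among 188.5. With 10 changed per run it recovered 1% at a size of 0.5 and 95% at a size of 1. The list test was run on 22180 simulated genes with 4 lists shifted by -0.2 and 20 left unshifted. At the preset correlation it called all 4 shifted lists and on average 0.05 of the unshifted ones per run. With an estimated correlation it called on average 3.95 of the 4 shifted lists. The simulated genes varied independently of each other, so this recovery need not hold for lists whose members vary together. The simulated spreads were those that the fit had already drawn towards a common value. Recovery in the real data may therefore be lower, and these shares do not bound how many real changes were missed.

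The alternatives set in advance were the replicate number as a block, quantile normalization again, centring each array on its median, 2 filters on level, an intensity trend with a robust prior, array weights, all probesets, a threshold of 0.01, a minimum of 1.5-fold, the mean of a gene's probesets, the other list tests and leaving out each array in turn. The alternatives chosen after seeing the data were the count of splits by size in the permutation test, the adjusted p of Lockd and Cdkn1b over all probesets, the lists without Cdkn1b, and the FoxO and quiescence list without the genes it shares with the glycolysis and hypoxia list. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.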

Results

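Gene expression was measured in G1E cells, an erythroid line of mouse origin that lacks functional GATA1 and grows as immature erythroid precursors. Control cells were profiled on 3 arrays and cells with a CRISPR/Cas9 deletion of Lockd on 4. Lockd is a long non-coding RNA gene next to Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27. The series title sets the long non-coding RNA apart from a cis element associated with it, and this comparison gives the transcripts that differed once Lockd was deleted. A deletion removes DNA as well as its transcript. With only control and deletion cells, an effect of the RNA cannot be told apart from one of the cis element. The 7 arrays correlated at between 0.993 and 0.996 over the tested probesets, and control replicate 2 stood apart on the first principal component, which held 29.9% of the variance.

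Markers of the line were compared between the groups, each with its own probeset, since levels of different probesets are not comparable. The erythroid genes Car2 and Gfi1b averaged 13.27 and 12.46 in control cells and 13.22 and 12.43 in deletion cells. Their differences were -0.04 (SE 0.06) and -0.03 (SE 0.07). The progenitor genes Gata2, Kit and Myb averaged 12.46, 11.74 and 12.16 in control cells and 12.42, 11.67 and 12.16 in deletion cells. Cpa3, a mast cell protease gene, averaged 11.15 ± 1.41 (SD, n = 3) in control and 10.45 ± 0.73 (SD, n = 4) in deletion cells. These 6 genes, each among the brightest measured of its list, were chosen after their values were seen, and none passed the test. They do not stand for the other members of their lists. Of the 44 measured erythroid genes, 7 had an unadjusted limma p under 0.05, 4 lower and 3 higher.

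Lockd, the targeted gene, fell on all 4 deletion arrays. It read 7.89, 8.04 and 7.80 in control replicates 1 to 3 and 5.09, 5.15, 4.17 and 5.15 in deletion replicates 1 to 4. The group means were 7.91 ± 0.12 (SD, n = 3) and 4.89 ± 0.48 (SD, n = 4), a difference of -3.02 (SE 0.23, 95% interval -3.54 to -2.49). That is 87.6% lower, with an interval of 82.2% to 91.4%. Without deletion replicate 3 the difference was -2.78. Whether the remaining 4.89 lies above background was not measured, and background may make the fall look smaller than it was. Cdkn1b, on the same chromosome 6, fell as well, from 9.18 ± 0.12 (SD, n = 3) to 8.03 ± 0.15 (SD, n = 4). Its difference was -1.14 (SE 0.10, 95% interval -1.37 to -0.91), or 54.7% lower with an interval of 46.9% to 61.4%, and all 4 deletion arrays, at 7.89 to 8.25, lay below the control arrays, at 9.06 to 9.30.

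In limma with Benjamini-Hochberg adjustment over 23521 probesets, the adjusted p was 0.0162 for Lockd and 0.0251 for Cdkn1b, the smallest and next smallest of all. The exact two-sided permutation test gave p = 0.0571 for each gene with the smaller tail doubled, and 0.0286 with splits counted by size, a form added after seeing the data, each the smallest that its form allows with 3 against 4 arrays. The calls had little margin, since leaving out control replicate 1, 2 or 3 or deletion replicate 1 or 4 put both genes above an adjusted p of 0.05, with differences between -3.10 and -2.95 for Lockd and between -1.20 and -1.08 for Cdkn1b. Without deletion replicate 3 Lockd passed and Cdkn1b did not, at an adjusted p of 0.118. With all probesets of the array tested in limma, the adjusted p was 0.0991 for Lockd and 0.141 for Cdkn1b. Where the Lockd probes lie relative to the deleted segment is not given in the sources used here.

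The neighbouring genes on both sides of Lockd and Cdkn1b did not pass the test. Apold1, next to Lockd on the side away from Cdkn1b, differed by -0.07 (SE 0.13), and Ddx47, an RNA helicase gene beyond it, by 0.00 (SE 0.07). On the Cdkn1b side, 2810454H06Rik, which is not among the listed neighbours, differed by 0.24 (SE 0.10) with an unadjusted limma p of 0.0381 and an adjusted p of 0.999. On the same side, Gpr19 differed by 0.06 (SE 0.10), Crebl2 by 0.03 and Dusp16, a MAP kinase phosphatase gene, by -0.06. Among the listed neighbours other than Cdkn1b, the differences ran from -0.30 (SE 0.15) for Gprc5a to 0.18 (SE 0.12) for Bcl2l14. Single arrays weighed on both ends, with Gprc5a at -0.19 without deletion replicate 1 and Bcl2l14 at 0.07 without control replicate 2 and 0.29 without control replicate 3. Etv6, a haematopoietic transcription factor gene, differed by 0.07, and the Wnt co-receptor gene Lrp6 by -0.11. Values were likewise small for Borcs5 at 0.03, Mansc1 at -0.05, Gprc5d at 0.07, Hebp1 at 0.03, Fam234b at 0.01, Emp1 at 0.03 and Grin2b at 0.04. The rest were Atf7ip at -0.02, Plbd1 at 0.00, Gucy2c at -0.08 and Wbp11 at 0.01. In limma, 0 of the 22 listed neighbours other than Cdkn1b passed adjusted over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05, Gsg1 at -0.21 and the histone gene H2aj at 0.18. The 95% intervals of these 22 genes lay between -0.65 and 0.46, which leaves smaller differences than that of Cdkn1b open. With Cdkn1b included, 13 of the 23 list members lay above the median level of all genes. At dimmer probesets, such as that of Bcl2l14 at 3.46 in control cells, background may hide a larger fall. The intervals do not bound a change there. The order of the genes is that of the assembly GRCm38.p6.

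**Figure D1:**
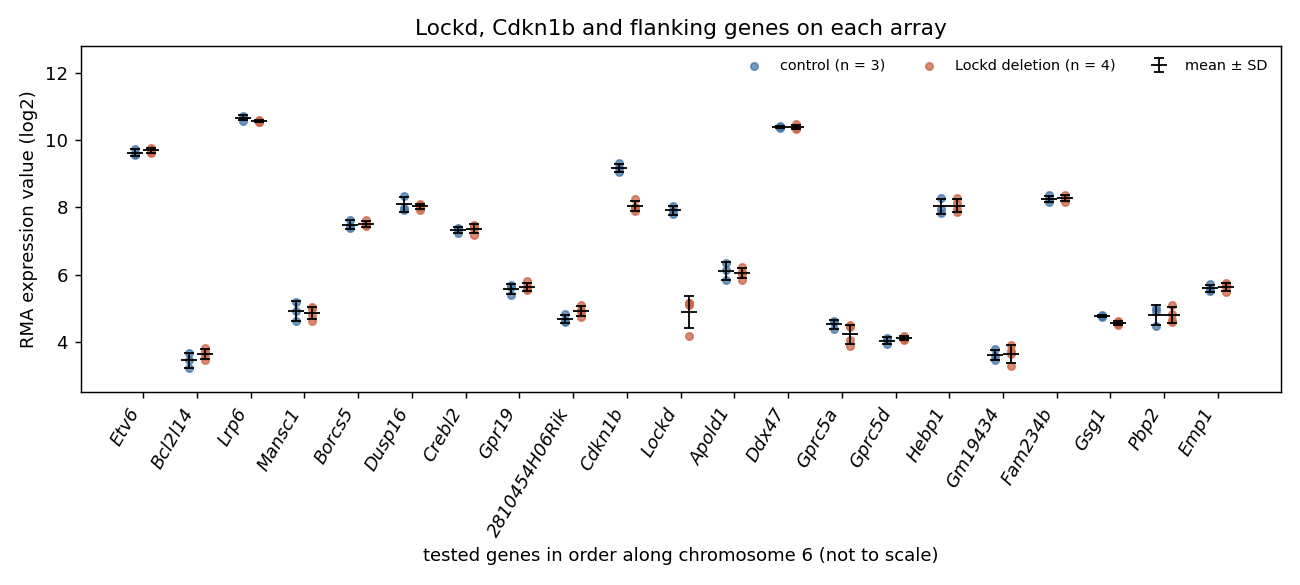
RMA expression values (log2, vertical axis) of Lockd, Cdkn1b and flanking tested genes in their order on chromosome 6 (horizontal axis, not to scale), with points for the 3 control and 4 deletion arrays and bars for mean ± SD. Lockd and Cdkn1b are lower on all deletion arrays, by -3.02 and -1.14 on average, and the other genes shown did not pass the test.

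Beyond this locus no probeset passed. The next smallest adjusted p was 0.236, for Abhd18, which was chosen for naming after its values were seen and differed by -0.55 (SE 0.07). The largest lower values among genes whose groups did not overlap were those of Tph1, the tryptophan hydroxylase of peripheral serotonin synthesis, at -2.03 (SE 0.29), and of Neurl3 at -1.25 (SE 0.31), Stk10 at -1.17 (SE 0.36), Jun at -0.90 (SE 0.20) and Ccng2 at -0.87 (SE 0.29). The largest higher values were those of Mfsd6 at 1.78 (SE 0.39), the phosphatase gene Ppm1e at 1.73 (SE 0.36), Enox2 at 1.25 (SE 0.40), Ppt2 at 0.81 (SE 0.16) and the transcription factor gene Pax9 at 0.69 (SE 0.13). Tph1 had an adjusted p of 0.516 in limma and the other 9 genes had values of 0.855 or more. Single arrays weighed heavily on some of these, with Stk10 at -0.72 without control replicate 1, Ccng2 at -0.57 without deletion replicate 3 and Enox2 at 0.82 without control replicate 3. Tph1 ranged from 9.35 to 10.39 on control and from 7.25 to 8.37 on deletion arrays.

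In limma with Benjamini-Hochberg adjustment, 2 probesets passed, both lower and 0 higher, and 1091 had an unadjusted p under 0.05, which is 4.64% of those tested. Of these 557 were lower and 534 higher in deletion cells. The groups did not overlap for 1151 genes, or 5.19%, where chance gives 5.71%, and 14 genes differed by 2-fold or more, Lockd and Cdkn1b included.

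**Figure D2:**
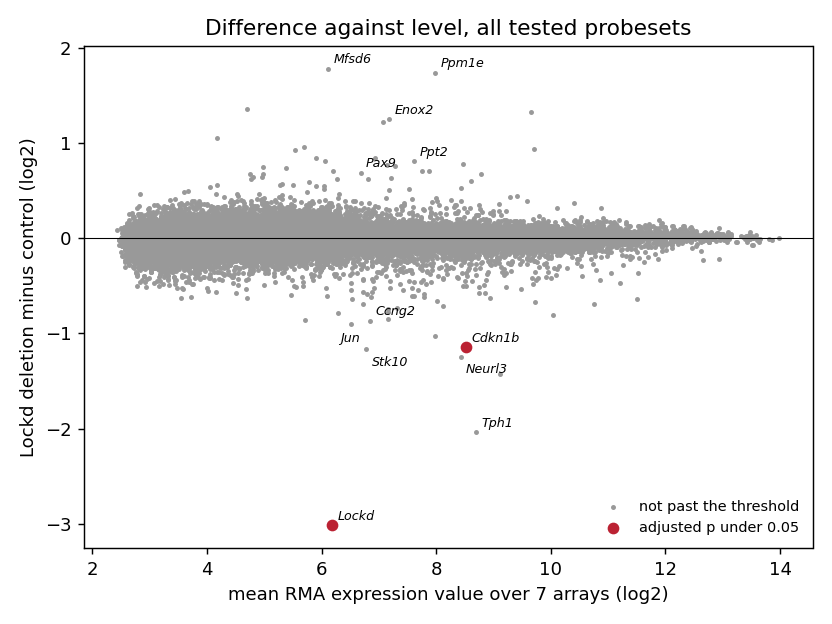
Deletion minus control (log2, vertical axis) against the mean RMA expression value over 7 arrays (log2, horizontal axis) of each tested probeset, with the 2 probesets past an adjusted p of 0.05 as large points. Lockd at -3.02 and Cdkn1b at -1.14 passed, whereas Tph1 at -2.03 did not.

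**Figure D3:**
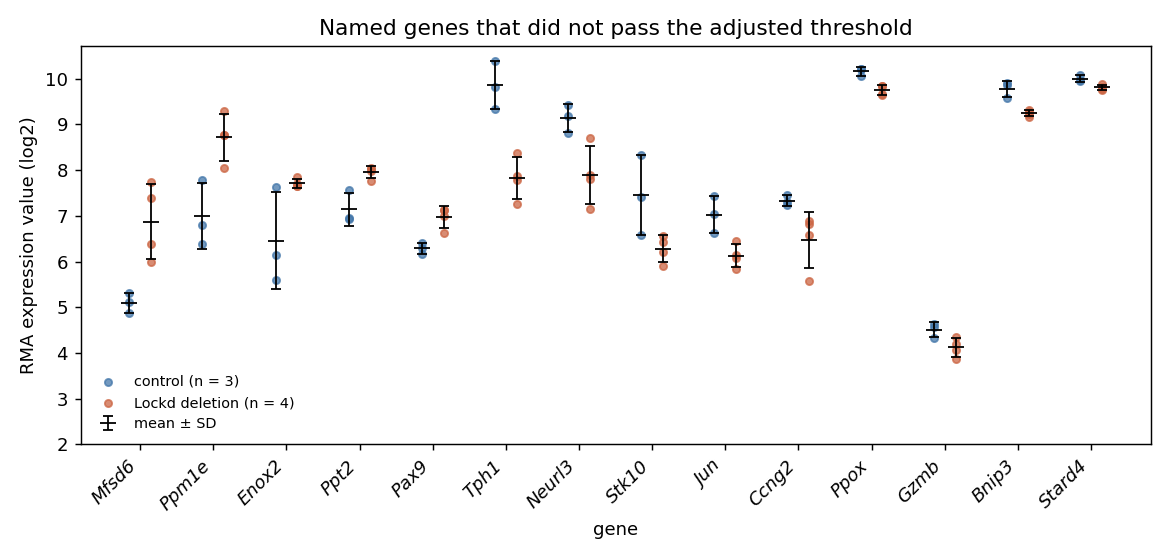
RMA expression values (log2, vertical axis) on each control (n = 3) and deletion (n = 4) array of named genes that did not pass the adjusted threshold (horizontal axis), with bars for mean ± SD. The control arrays of Stk10 and Enox2 are widely spread, and Bnip3 is lower on all deletion arrays by -0.54 on average.

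The genes of cell division were compared because Cdkn1b restrains cyclin-dependent kinases. Of the 8 CDK inhibitor genes, 6 were lower, but Cdkn1b alone passed, both over all genes and adjusted over the list alone. Cdkn1a, the p21 gene, differed by -0.07 (SE 0.10), Cdkn2d by -0.20 (SE 0.09) and Cdkn1c by 0.17 (SE 0.09). The list's median was -0.06, called lower by limma's camera with an adjusted p of 0.0260. It had adjusted p = 0.350 with an estimated correlation, and 0.374 at the preset correlation once Cdkn1b was left out. At the preset correlation it was not called without control replicate 1 (0.0746) or 3 (0.235) or deletion replicate 4 (0.0758).

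Genes of S phase were slightly higher without passing. Of 54 members, 43 were higher, with a median of 0.03, and Ubr7 had the smallest p at 0.17 (SE 0.08). Camera gave an adjusted p of 0.0776 at the preset correlation, and adjusted p = 0.839 with an estimated correlation. Leaving out each array in turn gave 0.000282 to 0.852 at the preset correlation, the lowest without control replicate 2, the array apart on the first component. Cyclins, CDKs and pocket proteins had a median of 0.00 over 27 members (camera adjusted p 0.914), with E2f7 at 0.14 (SE 0.08), and Ccnd2 and Cdk6 at -0.03 and 0.03. G2 and mitosis genes had a median of 0.01 over 57 members (camera adjusted p 0.882), with G2e3 at -0.16 (SE 0.07). In these lists of S phase, cyclin and G2 genes, 0 members passed in limma over all genes or adjusted over the list alone, and the members at an unadjusted p under 0.05 numbered 0, 0 and 1. Replication-dependent histone genes had a median of 0.01 over 21 members (camera adjusted p 0.670) and p53 target genes -0.03 over 31 (camera adjusted p 0.192). Their smallest p values were those of H2bc22, at -0.22 (SE 0.07), and Tnfrsf10b, at -0.19 (SE 0.08).

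Glycolysis and hypoxia genes were lower as a list in camera with adjusted p = 7.36e-08 at the preset correlation, but not past the threshold with an estimated correlation, at adjusted p = 0.350. Of 31 members 24 were lower, with a median of -0.11, below those of all 10000 random lists of like level, a comparison that leaves out how members vary together. Bnip3, a mitophagy receptor gene, differed by -0.54 (SE 0.09), the mitochondrial protein gene Higd1a by -0.38 (SE 0.08), the glucose transporter gene Slc2a1 by -0.37 (SE 0.11) and Vegfa by -0.29 (SE 0.12). In limma 0 members passed over all genes, 2 passed adjusted over the list alone, Bnip3 and Higd1a, and 10 had an unadjusted p under 0.05, all lower.

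Cholesterol biosynthesis genes were lower in 18 of 19 members, with a median of -0.14. Stard4, a sterol carrier gene, differed by -0.19 (SE 0.07), Mvd by -0.25 (SE 0.12) and Hmgcs1 by -0.22 (SE 0.11). Camera gave adjusted p = 4.78e-06 at the preset correlation, and adjusted p = 0.699 with an estimated correlation. The members varied together between arrays of the same group, with a mean pairwise correlation of 0.647, so the preset correlation may be too low for this list. Control replicate 1 was the lowest control array for all members but Pmvk and Insig1. Fdft1, for example, read 11.195 there and 11.064 to 11.361 on deletion arrays. Deletion replicate 4 was the lowest deletion array for all members but Stard4 and Nsdhl. Hmgcs1 read 11.577 on it and 11.738 to 11.93 on the other deletion arrays. In limma 0 members passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05.

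FoxO and quiescence genes were lower in 18 of 24 members, with a median of -0.06, and Bnip3, which is also in the glycolysis and hypoxia list, had the smallest p. Ccng2, a cyclin G gene of cell cycle exit, differed by -0.87 and Foxo3 by -0.19 (SE 0.08). In limma 0 members passed over all genes, 3 had an unadjusted p under 0.05 and 1, Bnip3, passed adjusted over the list alone. Camera gave adjusted p = 0.0212 at the preset correlation, and adjusted p = 0.350 with an estimated correlation. At the preset correlation the list was not called without the shared genes (0.0696), nor without control replicate 1 (0.0768) or 3 (0.0787) or deletion replicate 4 (0.0758).

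Heme biosynthesis and iron genes had a median of -0.02, with 14 of 24 members lower. Ppox, the protoporphyrinogen oxidase gene, differed by -0.41 (SE 0.08), Aco1 by -0.31 (SE 0.12) and Tfrc, the transferrin receptor gene, by -0.17 (SE 0.06). In limma 0 members passed over all genes, 1 passed adjusted over the list alone, Ppox, and 3 had an unadjusted p under 0.05. Camera gave adjusted p = 0.0495 at the preset correlation, and adjusted p = 0.699 with an estimated correlation. At the preset correlation the call was lost without control replicate 2 (0.390) or 3 (0.153) or deletion replicate 1 (0.138), 2 (0.105) or 4 (0.181). Erythroid genes had a median of -0.02 over 44 members and were not called (camera adjusted p 0.374), with Add2 at -0.44 (SE 0.12). In limma 0 of the 44 passed over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 7 of them, 4 lower and 3 higher, where 4.64% of all tested probesets were. The list had adjusted p = 0.850 with an estimated correlation, and leaving out each array gave 0.0120, without deletion replicate 3, to 0.958 at the preset correlation. Globin genes of the adult loci were not measured by a probeset with a single symbol.

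Mast cell and basophil genes were lower in 17 of 23 members, with a median of -0.13. Gzmb differed by -0.39 (SE 0.12), Rgs13 by -0.71 (SE 0.52) and Cpa3 by -0.70 (SE 0.62). The spread between arrays of the same group was wide for Cpa3, which read 9.53 on control replicate 2 and 11.95 or more on the other control arrays. Camera gave adjusted p = 0.0314 at the preset correlation, and adjusted p = 0.571 with an estimated correlation. In limma 0 members passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. At the preset correlation the call was lost without control replicate 1 (0.579) or 3 (0.0875) or deletion replicate 3 (0.0631) or 4 (0.181). Most members were dim, with 7 of the 23 above the median level of all genes and Gzmb at 4.51 in control cells. The call was also lost with values over 5 on 3 arrays (0.123) and with means above the median (0.160).

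Markers of other cell types were not called by camera at the preset correlation. The medians were 0.04 for megakaryocyte genes (adjusted p 0.607), -0.04 for myeloid (0.726), 0.01 for lymphoid (0.548), 0.08 for pluripotency (0.192) and 0.04 for stromal and endothelial genes (0.0921). Stromal and endothelial genes had adjusted p = 0.764 with an estimated correlation, and leaving out each array gave 0.0129, without control replicate 3, to 0.848 at the preset correlation. Examples were Gp9 at -0.33 (SE 0.11), Mpo at 0.24 (SE 0.08), Gzma at -0.30 (SE 0.09), Gdf3 at 0.23 (SE 0.10) and Tagln at 0.27 (SE 0.10). Progenitor genes had a median of 0.00 (0.726), with Hoxb4 at 0.39 (SE 0.10). Y-linked genes had a median of -0.05 (0.548), with Eif2s3y at -0.08 (SE 0.09).

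Stress and immune lists were not called either. Interferon response genes had a median of -0.03 (adjusted p 0.607), with Oas1b at -0.35 (SE 0.10), and MHC genes 0.06 (0.257), with Ciita at 0.25 (SE 0.10). The unfolded protein and integrated stress response list had a median of 0.02 (0.970), with Ddit4 at -0.33 (SE 0.14), and apoptosis regulators 0.01 (0.978), with Bmf at 0.30 (SE 0.11). Immediate early genes had a median of 0.00 (0.257), with Jun at -0.90, the 1 member that passed adjusted over the list alone. Ribosomal protein genes were higher in 50 of 58 members, with a median of 0.03 (0.20) and Rpl27 at 0.09 (SE 0.06). They had adjusted p = 0.850 with an estimated correlation. Leaving out each array gave 0.00745 to 0.848 at the preset correlation, with 0.00745 without control replicate 2 and 0.0470 without deletion replicate 2. In limma, over the 24 lists other than Lockd neighbours and CDK inhibitors, 0 of 687 distinct genes passed over all genes, and 42 had an unadjusted p under 0.05. Among the cell type, progenitor, Y-linked, stress, immune, histone, p53 and ribosomal lists, Jun was the only member that passed adjusted over the list alone.

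**Figure D4:**
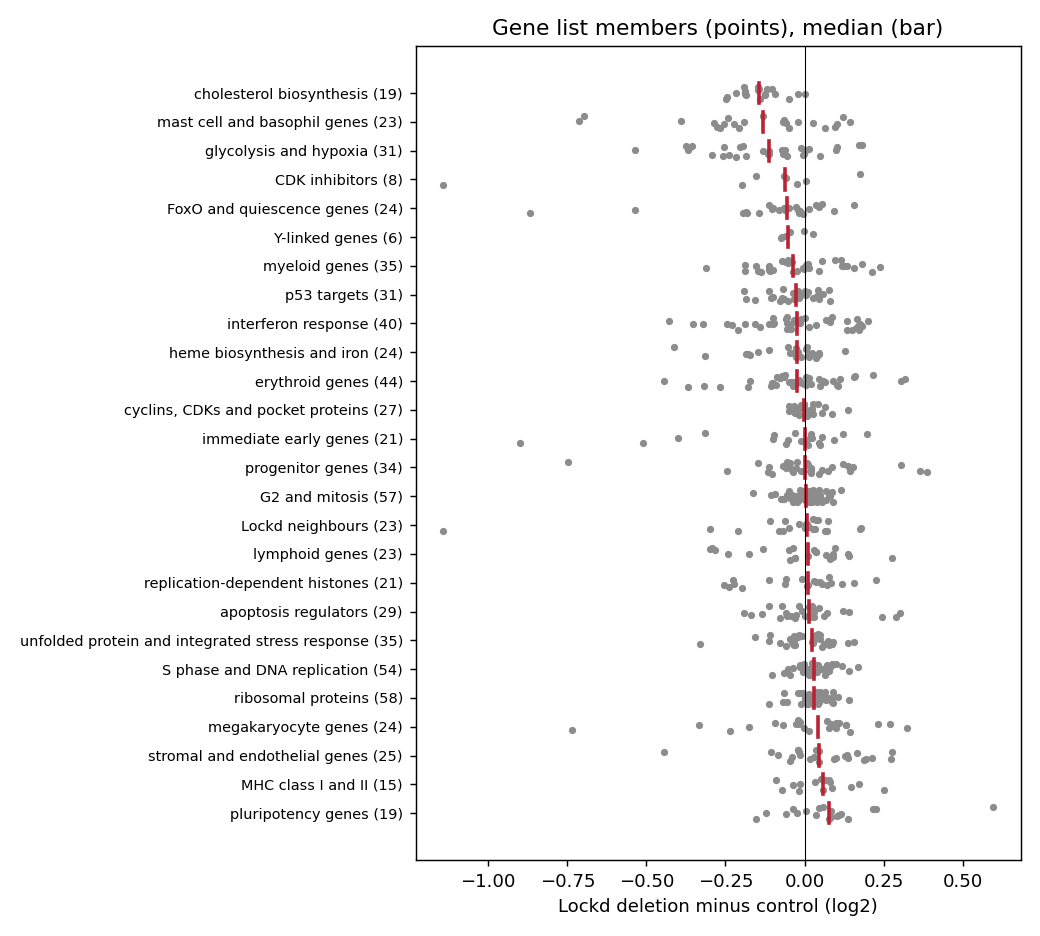
Deletion minus control (log2, horizontal axis) of the members of each gene list (vertical axis, number of measured genes in brackets), as points, with the median as a bar. The medians lie between -0.14 for cholesterol biosynthesis and 0.08 for pluripotency genes, and the point at -1.14 in 2 lists is Cdkn1b.

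Of the 26 lists, camera called 6 at the preset correlation, all lower. With an estimated correlation it called 0, the smallest adjusted p being 0.350, and 3 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in a single direction, called 0 with a smallest adjusted p of 0.136 and 5 lists at an unadjusted p under 0.05. The median, the mean and the test differed in sign for Lockd neighbours, cyclins with CDKs and pocket proteins, lymphoid genes, histones, apoptosis regulators, immediate early genes and the unfolded protein list, none of which was called.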

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

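The test of a trend with expression level and that of noise of dim probesets were chosen after the result was seen. The other tests given here were planned before their results were seen, although the array values of Lockd were known before its tests were set.

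Of 84 values and list means checked for a deletion array far from the other deletion arrays, 4 stood out, and chance flags about 1 in 20, or 4.2 of 84. All 4 were on deletion replicate 3. Lockd read 4.17 there and 5.09 to 5.15 on the other deletion arrays. The mean of the S phase and DNA replication list was 10.47, against 10.43 to 10.44. The mean of the myeloid list was 5.54, against 5.66 to 5.68. The mean of the replication-dependent histone list was 7.82, against 7.62 to 7.64.

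Lockd was lower on deletion replicate 3 than on the other deletion arrays by -0.96. A shift of dim values on that array is argued against, since 2235 genes of like level were lower there by a median of only -0.0422. No biological explanation was tested, as the labels give no difference between the deletion samples. Noise of dim probesets stays open, because 0.313% of the genes of like level ranged as widely over the deletion arrays and Lockd had been singled out from 84 items for such an array. A different extent of the deletion or a fault of single probes stays open as well.

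Glycolysis and hypoxia genes were lower as a list, with a mean of -0.13 and adjusted p = 0.350 with an estimated correlation. A trend with expression level is argued against, since the median lay at percentile 0 of the random lists of like level. The members varied together between arrays of the same group, with a mean pairwise correlation of 0.134, at the 99.6th percentile of 1000 matched random lists, so the preset correlation may be too low for this list. A mean of this size, 0.128 in either direction, was reached by 5 of 35 splits of the arrays into 3 and 4, the highest other being 0.146, so chance is not excluded. An effect of the deletion, the biological explanation in the design, also stays open. A difference between clones other than the deletion could not be told apart from it, as the labels do not say how clones and replicates relate.

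Mast cell and basophil genes were lower as a list, with a mean of -0.16 and adjusted p = 0.571 with an estimated correlation (0.614 with fry). Of the 23 members, 7 lay above the median level of all genes, so most of the list rests on dim probesets. The members varied together between arrays of the same group, with a mean pairwise correlation of 0.062, at the 95.8th percentile of matched random lists. A mean of this size, 0.156 in either direction, was reached by 14 of 35 splits, the highest other being 0.316, so chance is not excluded. An effect of the deletion, the biological explanation in the design, stays open, and here too a difference between clones could not be told apart from it.

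For the number of probesets past the threshold, 2 of the 35 splits gave as many as the real split, which gave 2. The highest of the others was 2, with control replicate 2 and deletion replicates 3 and 4 set against the rest, which called Adm2 and Cecr2. The count alone does not exclude chance. It says nothing of which genes passed, and Lockd and Cdkn1b had been singled out before the data were examined. For the number of gene lists, 10 of the 35 splits gave as many as the real 6, the highest other being 10 and the median of the others 3, so chance is not excluded.

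Probesets with several or no gene symbols were left out of the comparison. Of 17824 such probesets, 0 passed in limma, with a smallest adjusted p of 0.346 and 772 at an unadjusted p under 0.05.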

How the results depend on the processing

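The count of splits by size, the adjusted p of Lockd and Cdkn1b over all probesets, the lists without Cdkn1b and the FoxO list without shared genes were chosen after seeing the data. Lockd and Cdkn1b were lower in every setting run. Leaving out each array in turn gave -3.10 to -2.78 for Lockd (adjusted p 6.17e-05 to 0.106) and -1.21 to -1.08 for Cdkn1b (0.0342 to 0.189), and 0 to 2 probesets past the threshold. Both genes passed without deletion replicate 2. Without deletion replicate 3, Lockd passed with Cep126 (higher by 1.45, adjusted p 0.00775), a gene chosen after its values were seen. The exact permutation p was 0.0286 for both genes with splits counted by size, in place of 0.0571. With all probesets tested, 0 passed, with Lockd at -3.02 (adjusted p 0.0991) and Cdkn1b at -1.14 (0.141). The larger number of tests does not account for the whole of this rise in adjusted p. The unadjusted p-values rose as well, at unchanged differences. At an adjusted p of 0.01, 0 passed. The replicate numbers, those of the sample titles, gave no sign of pairing the samples. With the group means taken out, same-numbered arrays correlated at 0.0248, 0.0611 and -0.098, and not every array correlated best with its own number. So few pairs cannot exclude a pairing. The description labels number the deletion samples higher by 1. That would set control replicates 2 and 3 beside deletion replicates 1 and 2, whose arrays correlated on this measure at -0.171 and -0.0994. A block by those numbers was not run. The replicate block by title gave 0 probesets, with Lockd at -3.10 (0.109) and Cdkn1b at -1.14 (0.680), and 2 lists. With it the adjusted p was 0.0885 for CDK inhibitors, 0.0764 for FoxO and quiescence and for mast cell genes, and 0.215 for heme and iron. Deletion replicate 4 has no control of its number, so in this block it adds nothing to the differences of Lockd and Cdkn1b, which equal those without it. The block also leaves less data to estimate the spread, so the lost calls do not by themselves show a replicate effect.

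The count of called lists was 0 with an estimated correlation and 0 with fry, and 2 to 7 on leaving out arrays, with 3 without control replicate 1 or 3 and 2 without deletion replicate 4. With an estimated correlation the adjusted p was 0.350 for CDK inhibitors, FoxO and quiescence, and glycolysis and hypoxia, 0.699 for cholesterol biosynthesis and for heme and iron, and 0.571 for mast cell genes. With fry these were, in turn, 0.136, 0.241, 0.166, 0.614, 0.614 and 0.614. CDK inhibitors without Cdkn1b had 0.374 and the FoxO list without shared genes 0.0696. Heme and iron had 0.201 with array weights and 0.0523 with the mean of a gene's probesets. Mast cell genes had 0.123 with values over 5 on 3 arrays and 0.160 with means above the median. Lists newly past the threshold were ribosomal proteins with array weights (0.0113), S phase with array weights (0.00914) and with means above the median (0.0309), and stromal and endothelial genes with centred arrays (0.0449) and with values over 5 on 3 arrays (0.0368). Leaving out arrays gave 0.00762 to 0.235 for CDK inhibitors, 0.00327 to 0.0787 for FoxO and quiescence, 0.00451 to 0.390 for heme and iron and 0.00327 to 0.579 for mast cell genes. The ranges were 0.0120 to 0.958 for erythroid, 0.00745 to 0.848 for ribosomal protein, 0.000282 to 0.852 for S phase and 0.0129 to 0.848 for stromal and endothelial genes. Glycolysis and hypoxia stayed called, at 3.30e-08 to 7.89e-05, and so did cholesterol biosynthesis, at 3.30e-11 to 0.0237. All of these ranges are at the preset correlation of 0.01. The mean pairwise correlation within groups was 0.134 for glycolysis and hypoxia and 0.647 for cholesterol biosynthesis, so these ranges do not show that the calls are secure. Where no reason is given the cause was not tested. Of 729 alternative values of 54 other named genes, all stayed on their side of the threshold, and 34 changed sign with neither value past it. Among others, leaving out an array moved E2f7 to 0.08, Mpo to 0.15, Tagln to 0.18, Rpl27 to 0.06 and Eif2s3y to -0.02, a change of over 1.5 times, besides Stk10, Ccng2 and Enox2. There were 16 lists past the threshold in no setting. RMA values carry no measure of signal over background, so what dim probesets can show is not known.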

Other observations

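The test of genes that stand apart on a single array was set up after such genes had been seen, and it had too few genes to decide anything, so its result is not used.

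Some genes that did not pass the test between the groups set single arrays apart. Uprt, an X-linked gene, read 3.94 on deletion replicate 4 and averaged 9.98 ± 0.15 (SD) on the other 6 arrays. Tbc1d19 and Dppa4 read 4.59 and 6.34 on control replicate 3 and averaged 7.32 and 8.98 on the others. Zfp827 read 4.56 on deletion replicate 3 and averaged 6.85 on the others, and Pclaf read 7.48 on deletion replicate 4 against 5.03. These 5 genes had a gap of at least 2 on the log2 scale to the nearest other array, with the other arrays within a range of 1, limits that were set after the data were seen.

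The cholesterol biosynthesis genes moved together between arrays of the same group, with a mean pairwise correlation of 0.647 against a median of 0.0363 in matched random lists. The corresponding values were 0.253 for the unfolded protein and integrated stress response list, 0.237 for S phase, 0.213 for p53 targets and 0.194 for ribosomal protein genes. CDK inhibitors, at -0.0181, lay near the median of their random lists, -0.00836. Correlations are across genes of the list, which are not independent replicates.

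Gata1, the gene that G1E cells lack in functional form, had a probeset at 9.18 ± 0.08 (SD, n = 3) in control and 9.29 ± 0.09 (SD, n = 4) in deletion cells. Where its probes lie relative to the altered part of the gene is not given in the sources used here. The Y-linked genes Kdm5d, Uty and Eif2s3y averaged 3.41, 3.47 and 3.71 in control cells and 3.41, 3.41 and 3.63 in deletion cells. The embryonic globin genes Hbb-y and Hbb-bh1 averaged 4.60 and 5.23 in control cells and 4.55 and 5.22 in deletion cells. Slc4a1, the red cell anion exchanger gene, varied between 7.40 and 8.84 over the 7 arrays.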
